A study of Homo sapiens with 4 samples.

How the data were processed

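Transcripts were measured in KELLY cells, an established human neuroblastoma line with amplified MYCN, infected with an inducible lentiviral vector that carried a hairpin RNA. The 2 groups were cells with a non-targeting hairpin (shNT) and cells with a hairpin against BPTF (BPTF sh2), with 2 libraries each. Per the labels' protocols, doxycycline at 1 µg/mL for 48 h switched on the hairpin, total RNA was extracted, and libraries were made with a QuantSeq 3′ forward kit, which reads a short tag near the 3′ end of each polyadenylated transcript. The labels conflict for shNT: the treatment protocol gives doxycycline for all samples, while the sample characteristic of both shNT libraries says vehicle. If the second is right, the hairpin and doxycycline cannot be told apart in this comparison.

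The authors deposited raw read counts per gene symbol, with no normalization, in a table of 23368 genes by 4 libraries. Bowtie, TopHat, HTSeq and the genome build hg19 are named in the submitters' processing notes, without versions. The strand setting of the counting, the gene annotation and any read filter are not given in the sources used here. Tags that fit several near-identical genes could have been dropped or split, so values of genes with such copies are uncertain. Not every such gene is marked below. Unmarked ones include CKS1B, PCNA, FEN1, UNG, MTHFD2, SLC7A5, HK2, CCNG2 and CHD2. A gene and an overlapping antisense gene can be told apart only if the counting used strand. No mitochondrially encoded gene has a row in the table used here, and 5898 genes had a count of 0 in every library.

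Library totals were 8077950 and 7177545 counts in shNT and 5130275 and 7073339 in BPTF sh2. A count of 3, the upper limit that a count of 0 allows, corresponds to between 0.371 and 0.585 CPM (counts of a gene per 1000000 counts of the library), for counting error only. Column names of the count table were matched to sample titles, and the replicate number is the experiment number in the title. The design text describes the replicates as biological. Counts differed between replicates by more than sampling noise in both groups, with a chi-square per gene of 5.94 in shNT and 24.7 in BPTF sh2, over genes with at least 20 counts in the pair, so no library was taken for a copy of another.

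Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 12237, and scaled by TMM, with factors from 0.981 to 1.03. The groups were compared with the quasi-likelihood F-test (glmQLFit and glmQLFTest), with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F, and 95% intervals used the total degrees of freedom of the test. CPM values are relative to TMM-scaled library sizes, except for genes that were not tested, where they are relative to the library total. The biological coefficient of variation was 18.3%, and the median log2 fold change of all tested genes was 0.02.

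Gene lists were fixed before the data were examined: 27 lists for a MYCN-amplified neuroblastoma line, a chromatin remodeller knockdown, cell cycle and cell state, stress and doxycycline exposure, RNA quality and cell types that the culture should lack. Lists with at least 5 tested members, 22 in all, were tested with camera (limma 3.58.1), which compares a list's members with all other genes, at a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry, which asks whether the members move on balance one way. The estimated version rests on the few residual degrees of freedom that 4 libraries leave, so it had little power. Its smallest adjusted p over the 22 lists was 0.826. For cell cycle inhibitors the estimated correlation was −0.044, below the preset, yet the camera p went from 0.0095 to 0.109. A call lost there does not by itself show that the call was false. Named genes also followed a rule set before the data were examined: BPTF; MYCN, MYC, HAND2, GATA3, CCND1 and CDKN1A at any value; the 10 largest and 10 smallest fold changes among called genes with a mean of at least 10 CPM and groups that did not overlap; and up to 4 tested members of each list with the smallest p. Genes named outside it are marked as such. A few genes that the rule selects are not reported here.

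The tests were checked on simulated counts for this comparison of BPTF sh2 with shNT, drawn for 12237 genes from the real means, library sizes and dispersions. The changed genes were drawn from those with an average above 10 CPM, so recovery at lower levels was not shown. Of 100 genes changed by a log2 fold of 1, edgeR recovered 59. Of 100 changed by a log2 fold of 2 it recovered 97, with 17 false calls. In this draw the false calls were a larger share of all calls than the threshold of 0.05 aims at. On 12063 genes, 1 list of 50 genes was shifted by 0.5 on the log2 scale. Camera called that list and 0 of 22 unshifted lists. These draws had independent genes and 1 dispersion per gene for both groups. They could not show false list calls from correlated genes, nor recovery under the larger spread between the BPTF sh2 libraries.

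Alternatives set before the data were examined were size factors from DESeq2 1.42.0, library size alone, no filter, a filter at a mean of 10 CPM, the DESeq2 Wald test, the legacy edgeR fit, the experiment number as a replicate block, leaving out each library, leaving out ribosomal protein genes, and an estimated correlation. Others were added after the data were seen: an adjusted p of 0.1, thinning every library to the smallest total, leaving out genes with near copies, and removing from each library a loess trend on transcript length and GC content, with a span of 0.3. Transcript length, GC content and near copies came from GENCODE 29 (assembly GRCh38), in which 20194 symbols were found directly and 1480 through an older symbol, with 1694 unmatched. A near copy was another gene's transcript at 90% identity or more over at least 350 nt, or over 60% of a shorter transcript, found with BLAST 2.17.0, or a pseudogene named after the gene. Since that assembly is not the one the authors named, no coordinates are given. Plots were drawn with matplotlib 3.10.9.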

Results

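Gene expression was measured by 3′ tag sequencing in KELLY neuroblastoma cells carrying a doxycycline-inducible hairpin, with 2 shNT control libraries and 2 BPTF sh2 libraries. The libraries held 8077950 and 7177545 counts in shNT and 5130275 and 7073339 counts in BPTF sh2, and 12237 genes were tested. The comparison asks what loss of BPTF, the largest subunit of the NURF chromatin remodelling complex, does to transcript levels in cells driven by MYCN. The treatment of the shNT cells is labelled both as doxycycline and as vehicle, so a part of any difference could lie with doxycycline itself.

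BPTF, the target of the hairpin, stood at 1122 and 1048 CPM in the shNT libraries and at 980 and 643 CPM in BPTF sh2 libraries 1 and 2. Both BPTF sh2 libraries lay below both controls, at a mean of 811 ± 238 CPM against 1085 ± 52.2 CPM (SD, n = 2 each). BPTF was thus at 74.8% of the control level, a log2 fold change of −0.42 with an SE of 0.22, which did not pass the test (edgeR adjusted p = 0.378). The reduction came mainly from library 2: without BPTF sh2 replicate 1 the log2 fold change was −0.76, and without replicate 2 it was −0.15. Such fits leave 1 library in a group, so their error rests on the other group, and their p-values are left out here. BPTF has 3 near copies in the reference annotation, which could take or add tags, so its level is uncertain.

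MYCN, the amplified oncogene of this line, averaged 2362 ± 115 CPM in shNT and 1140 ± 402 CPM in BPTF sh2 (SD, n = 2 each). The 4 values were 2281 and 2443 CPM against 1424 and 856 CPM, a log2 fold change of −1.05 with an SE of 0.24 and a 95% interval from −1.59 to −0.51. This difference did not pass correction over all genes in the main test (edgeR adjusted p = 0.118). The DESeq2 Wald test called it (DESeq2 adjusted p = 0.00552). So did edgeR with the experiment number as a replicate block (adjusted p = 0.00134), a pairing that is not established. That fit also drew each gene's variance wholly to the trend over all genes. Its prior degrees of freedom were infinite, against 8.61 in the main fit. For MYCN the log2 fold change was −1.47 without BPTF sh2 replicate 1 and −0.73 without BPTF sh2 replicate 2. It was −1.10 without shNT replicate 1 and −1.02 without shNT replicate 2. MYC itself was almost silent, with counts of 1 and 0 in shNT and 2 and 0 in BPTF sh2, and was not tested.

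Among the transcription factors of the adrenergic neuroblastoma state, PHOX2A showed the largest difference relative to its error. It measured 478 and 507 CPM in shNT and 299.5 and 191 CPM in BPTF sh2 (log2 fold change −1.01, SE 0.22, edgeR adjusted p = 0.109). DESeq2 called it (DESeq2 adjusted p = 0.00724), and so did edgeR with the replicate block (adjusted p = 0.000509). With 1 library left out, its log2 fold change ran from −1.37 without BPTF sh2 replicate 1 to −0.72 without BPTF sh2 replicate 2. INSM1, a factor of neuroendocrine cells, had a log2 fold change of −1.61 with an SE of 0.42 at 16.7 CPM in shNT and 5.62 CPM in BPTF sh2. HAND2 averaged 534 ± 4.98 CPM in shNT and 374.5 ± 66.7 CPM in BPTF sh2 (log2 fold change −0.51, edgeR adjusted p = 0.237), and SATB1 had a log2 fold change of −0.53. The core factor GATA3 stayed near its control level, at a log2 fold change of −0.05 (95% interval −0.43 to 0.34). Of the 21 adrenergic factors, 15 had a lower mean and 6 a higher one, with a median log2 fold change of −0.19. None was called over all genes by edgeR and 1 by DESeq2, 5 lower and 1 higher had an unadjusted p below 0.05, and 2 were lower when adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.170, and 0.826 with an estimated correlation). Without the filter on low counts the adjusted p at the preset correlation was 0.0499.

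**Figure D1:**
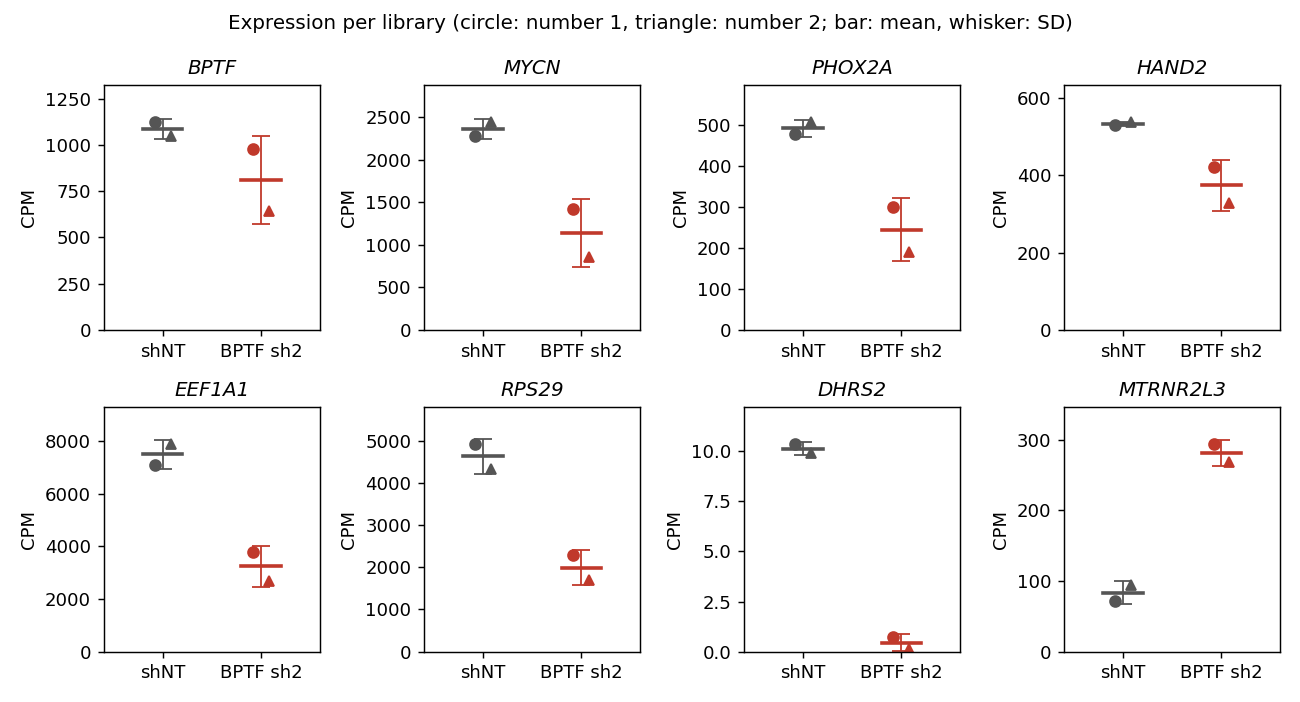
Expression in CPM (linear vertical axis from 0) of 8 genes in each library, with shNT in grey and BPTF sh2 in red, where circles are libraries with number 1, triangles those with number 2, horizontal bars the group mean and whiskers the SD of 2 libraries. MYCN lay at 2281 and 2443 CPM in shNT against 1424 and 856 CPM in BPTF sh2, while BPTF itself was at 980 CPM in BPTF sh2 library 1, close to the controls at 1122 and 1048 CPM.

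Over the whole transcriptome, 1 gene was called higher and 1 was called lower in BPTF sh2. DHRS2, a short-chain dehydrogenase, fell from counts of 82 and 71 in shNT to 4 and 1 in BPTF sh2, a log2 fold change of −4.57 with an SE of 0.58 (edgeR adjusted p = 0.0498). It is named after its values were seen, since its mean lies below 10 CPM. MTRNR2L3 rose from 72.0 and 94.7 CPM to 294 and 268 CPM, a log2 fold change of 1.75 with an SE of 0.20 (edgeR adjusted p = 0.0398). It belongs to a family of nuclear copies of the mitochondrial 16S ribosomal RNA gene, so its tags may come from elsewhere and its value is uncertain. Without the filter on low counts neither gene was called (edgeR adjusted p = 0.0660 for both). At an unadjusted p below 0.05 there were 772 higher and 1130 lower genes. The groups did not overlap for 5958 genes, 48.7% of those tested, where chance gives 33.3% for exchangeable libraries. Genes of the same libraries move together, so the excess alone does not show a group difference. The DESeq2 Wald test called 14 higher and 163 lower genes. With a lone library assumed to vary like the other group, the edgeR counts were 1357 higher and 1667 lower without BPTF sh2 replicate 1, 518 and 636 without BPTF sh2 replicate 2, 1 and 49 without shNT replicate 1, and 3 and 18 without shNT replicate 2.

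At an adjusted p below 0.1, a threshold added after the data were seen, edgeR listed 73 lower and 9 higher genes, of which DESeq2 called 69 and 9 at 0.05. The genes named from this set were chosen after their values were seen, and are named singly, not as groups. SDHC of respiratory complex II had a log2 fold change of −1.30, the complex I subunits NDUFB5, NDUFB3 and NDUFA1 had −1.22, −2.03 and −0.95, and COX6C of complex IV had −1.07. Thioredoxin TXN had −1.35 and the peroxiredoxin PRDX3 −1.49. SEC61G and SEC61B, subunits of the channel that takes proteins into the endoplasmic reticulum, had −1.54 and −1.12. The thymosin TMSB4X and the profilin PFN1 had −2.22 and −1.21. The spliceosome component SNRPA1 had −1.53 and the translation elongation factor EEF1A1 had −1.21, at 7500 ± 558 CPM in shNT and 3249 ± 776 CPM in BPTF sh2 (SD, n = 2 each). On the higher side, the small nucleolar RNA SNORD50A had 1.40, the neuronal pentraxin receptor NPTXR 1.05 and SAMD1 1.24. The kit is made for polyadenylated transcripts, so tags at SNORD50A need not measure the mature small RNA. SNORD50A also had no match in the annotation used for near copies. Many of the lower genes have near copies in the genome, and their values are uncertain for that reason. Among them are EEF1A1, TMSB4X, TXN, PFN1, COX6C, SDHC, NDUFB5, PRDX3 and SNRPA1.

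Genes of the cell cycle and MYC targets went both ways, and none was called over all genes by edgeR, nor by DESeq2 apart from 2 lower MYC targets. The 43 tested G1/S genes had a median log2 fold change of 0.04 (24 higher, 19 lower, camera adjusted p = 0.957), and 3 higher and 4 lower had an unadjusted p below 0.05, with CDCA7, FEN1 and PCNA at −0.66, −0.67 and −0.49 and the uracil glycosylase UNG at 0.58. The 54 G2/M genes had a median of −0.03 (25 higher, 29 lower, camera adjusted p = 0.957), and 3 higher and 7 lower had an unadjusted p below 0.05, with the kinase subunit CKS1B at −0.64 and the centromeric histone CENPA at −0.91. The 22 cyclins, CDKs and E2F factors had a median of 0.03 and a mean of −0.01 (camera adjusted p = 0.981), with 1 higher and 4 lower at an unadjusted p below 0.05 and MYBL2 at 0.57. No member of these 3 lists was past the threshold when adjusted over the list alone. CCND1, which encodes cyclin D1, was at 0.10 with a 95% interval from −0.31 to 0.50, and the inhibitor CDKN1A at 0.13 with an interval from −0.45 to 0.72. The 16 cell cycle inhibitors had a median of −0.35 (camera adjusted p = 0.0696, and 0.826 with an estimated correlation). At the preset correlation the adjusted p was 0.0231 without the filter on low counts, and 0.431 with a filter at a mean of 10 CPM. Of the members 10 were lower and 6 higher, 6 of the lower at an unadjusted p below 0.05. Of these CCNG2 had a log2 fold change of −1.14, the only member lower when adjusted over the list alone, while CDKN2A had −0.90 and BTG2 −0.91. The 58 MYC targets had a median of −0.03, 31 lower and 27 higher, of which 6 and 7 had an unadjusted p below 0.05 (camera adjusted p = 0.957). RCL1 at −1.76 and hexokinase HK2 at −1.31 were lower when adjusted over that list alone.

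Transcripts of cytosolic ribosomal proteins fell as a list by camera at the preset correlation (median log2 fold change −0.21, 58 of 78 members lower, adjusted p = 1.57e-06). The call was lost with an estimated correlation (camera adjusted p = 0.826), a test with little power at 4 libraries. No member was called over all genes by edgeR and 9 were called lower by DESeq2, 23 lower and 0 higher had an unadjusted p below 0.05, and 16 were lower when adjusted over the list alone. RPS29 stood at 4629 ± 410 CPM in shNT and 1991 ± 408 CPM in BPTF sh2 (SD, n = 2 each), a log2 fold change of −1.22, and RPS7, RPL30 and RPL27 were at −0.96, −0.82 and −0.95. Within BPTF sh2, RPS29, RPS7 and RPL27 were lower in library 2 (1703, 986 and 497 CPM) than in library 1 (2280, 1264 and 781 CPM). RPL30 went the other way, with 861 CPM in library 1 and 953 CPM in library 2. The pattern by library given next for the list thus does not hold for each member. All tested members have near copies in the reference annotation, so these values are uncertain. The list took 16.3% and 16.0% of the counts in shNT and 12.2% and 15.8% in BPTF sh2, so BPTF sh2 library 1 stood apart. Without that library the list was not called (camera adjusted p = 0.470).

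Chromatin remodellers outside the BPTF complexes were higher as a list by camera (median log2 fold change 0.29, 17 of 21 members higher, adjusted p = 0.0104). This call too was lost with an estimated correlation (camera adjusted p = 0.826), where little power was left. No member was called by DESeq2 or by edgeR, over all genes or adjusted over the list alone, and 5 higher and 0 lower members had an unadjusted p below 0.05. The chromodomain helicases CHD3, CHD2 and CHD6 were at 0.51, 0.44 and 0.40 and INO80 at 0.53. Their transcripts are long, with a median of 7962 nt against 3301 nt over the tested genes. After removal of a trend on length and GC content the median was 0.22, with 4 members lower as before. The 95% bootstrap interval over member genes was 0.10 to 0.30, against 0.22 to 0.40 before. Member genes are not independent replicates, so these intervals leave out the spread between libraries. The list missed the threshold after this removal (camera adjusted p = 0.0647). That call ended with a smaller fold and not with a wider error, the median SE of the members being 0.19 before and 0.16 after, and the role of length stays open. The list also missed the threshold without shNT replicate 2 (camera adjusted p = 0.0800), without BPTF sh2 replicate 1 (0.267) and without genes that have near copies (0.0606). Among the 12 tested BPTF partners and ISWI subunits, the median was 0.16 (camera adjusted p = 0.229, and 0.847 with an estimated correlation). Against the shNT library of the same number, it was 0.31 in BPTF sh2 library 1 and 0.05 in library 2. HMGXB4, an HMG box protein associated with NURF, was at 0.75, higher when adjusted over the list alone, the bromodomain protein BAZ1B was at 0.53 and the ISWI ATPase SMARCA1 at −0.46.

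**Figure D2:**
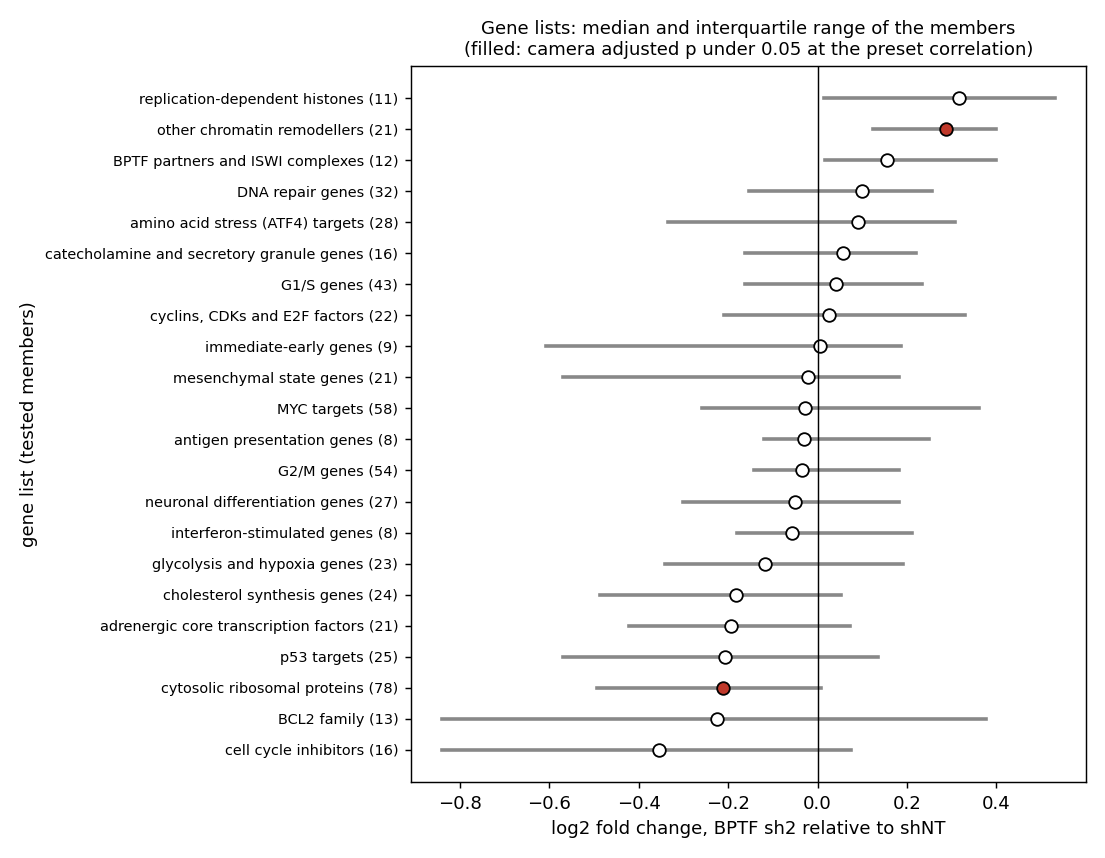
Median log2 fold change of BPTF sh2 relative to shNT (points) and interquartile range of the members (lines) for the 22 tested gene lists, with the number of tested members in parentheses and filled points for lists with a camera adjusted p below 0.05 at the preset correlation. The 2 filled lists are cytosolic ribosomal proteins, with a median of −0.21, and other chromatin remodellers, with 0.29. Neither was called with an estimated correlation, a test with little power at 4 libraries.

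Neuronal and cell state genes gave no list that passed camera. The 27 neuronal differentiation genes had a median log2 fold change of −0.05 (adjusted p = 0.487). The neuronal microtubule protein DCX and the axon guidance mediator CRMP1, at −0.83 and −0.82, were lower when adjusted over that list alone. The 16 catecholamine and secretory granule genes had a median of 0.06 and a mean of −0.06 (adjusted p = 0.981), with the granins SCG2 at 0.56 and SCG5 at −0.65. The 21 tested mesenchymal state genes had a median of −0.02 (adjusted p = 0.401). SIX4 and COL6A3, at −1.66 and −1.88 and under 10 CPM, were lower when adjusted over that list alone.

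Stress, survival and metabolic lists did not pass camera either. Medians were −0.21 for 25 p53 targets (adjusted p = 0.401), −0.23 for 13 BCL2 family members (0.286), 0.10 for 32 DNA repair genes (0.957) and 0.09 for 28 amino acid stress targets of ATF4 (0.981). The survival factor MCL1 was at −0.84, the recombination ATPase RAD54L at −1.68, the amino acid transporter SLC7A5 at 0.55 and the folate enzyme MTHFD2 at −0.55. The 24 cholesterol synthesis genes had a median of −0.18, 15 lower and 9 higher (camera adjusted p = 0.0887, and 0.826 with an estimated correlation). Without the filter on low counts the adjusted p at the preset correlation was 0.0263. IDI1, at −1.21, was the member lower when adjusted over the list alone, and HMGCS1 was at −0.57. The 23 glycolysis and hypoxia genes had a median of −0.12 (camera adjusted p = 0.401, and 0.982 with an estimated correlation). Against the shNT library of the same number, their medians in BPTF sh2 libraries 1 and 2 were −0.32 and 0.05. Those of cholesterol synthesis genes were −0.24 and −0.15. The remaining medians were 0.01 for 9 immediate-early genes (0.519), 0.32 for 11 replication-dependent histones (0.218), −0.06 for 8 interferon-stimulated genes (0.912) and −0.03 for 8 antigen presentation genes (0.957). The means of the immediate-early and interferon lists, −0.28 and 0.18, differ in sign from their medians. The DNA repair and ATF4 target lists do so too, with means of −0.01 and −0.04. Adjusted over each list alone, 2 immediate-early genes, among them NR4A1 at −2.70, and 1 glycolysis gene, HK2, were lower. NR4A1 rests on low counts, 29 and 21 in shNT against 5 and 1 in BPTF sh2. No p53, BCL2, DNA repair, ATF4, interferon, antigen presentation or histone gene passed in that way. The histone list passed camera at the preset correlation without the filter (adjusted p = 0.0499). With the filter and an estimated correlation its camera adjusted p was 0.909. Against the shNT library of the same number, its medians in BPTF sh2 libraries 1 and 2 were 0.06 and 0.56. The kit is made for polyadenylated transcripts, so the histone values need not reflect total histone transcript.

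Few markers of cells that the culture should lack passed the filter on low counts. PMP22 of the Schwann cell list reached 17.6 CPM. CD74 of the immune list reached 16.2 CPM, KRT19 of the epithelial list 4.54 CPM and EMCN of the endothelial list 1.53 CPM. Their log2 fold changes were 0.25 for PMP22, −0.20 for CD74, 0.08 for KRT19 and −0.63 for EMCN, and none was called by edgeR. SOX10, CD3E and CDH5 had counts of 0 in every library.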

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

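Alternatives set before the data were examined come first. The BPTF log2 fold change was negative under each, from −0.76 to −0.15 when 1 library was left out. Calls of higher and lower genes depended on the setting. There were 1 and 2 with DESeq2's size factors, 0 and 0 without a filter or with a mean of at least 10 CPM, 14 and 163 with the DESeq2 Wald test, 1 and 0 with the legacy edgeR fit, and 1 and 2 without ribosomal protein genes. Leaving out 1 library gave 1 to 1357 higher and 18 to 1667 lower genes, largest without BPTF sh2 replicate 1. With the experiment number as a replicate block, 62 higher and 383 lower genes were called, and BPTF had a log2 fold change of −0.45 (edgeR adjusted p = 0.327), with MYCN and PHOX2A called (0.00134 and 0.000509). Among the named genes other than BPTF, with MYCN and PHOX2A counted, 20 became called under the block and 10 with DESeq2. The block fit took each gene's variance wholly from the trend over all genes, so its calls rest on that assumption too. The labels do not say that the number marks a shared day, and the same-number deviations correlated across genes at 0.0476 (Spearman −0.0024), so the pairing is not established. These counts were seen together with that correlation.

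Lists called by camera numbered 2 in the main analysis, 6 without a filter (cell cycle inhibitors, adrenergic factors, cholesterol synthesis genes and histones added), 1 without ribosomal protein genes, 0 with an estimated correlation and 0 to 5 when 1 library was left out, and fry called 0 of 22. Of settings chosen after the data were seen, an adjusted p of 0.1 gave 9 higher and 73 lower genes, thinning to the smallest total 0 and 0, leaving out near copies 2 and 16 with 0 lists, and removing the length and GC trend 1 and 0 with 1 list. The cause of these moves was not tested, apart from the fewer genes or samples in a setting.

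Lists near 0 changed direction, all with adjusted p-values far from the threshold. Without a filter these were G1/S and DNA repair genes (both 0.989), with a mean of at least 10 CPM catecholamine genes (0.916) and ATF4 targets (0.948), after thinning catecholamine genes (0.986), without near copies G2/M genes (0.949), and with the length and GC trend removed G2/M genes (0.457). Leaving out 1 library turned some directions, with camera adjusted p-values over those fits of 0.474 to 0.901 for G1/S genes, 0.323 to 0.894 for G2/M genes, 0.786 to 0.901 for cyclins, CDKs and E2F factors, 0.197 to 0.929 for MYC targets, 0.126 to 0.901 for catecholamine genes, 0.307 to 0.901 for DNA repair genes, 0.251 to 0.933 for ATF4 targets, 0.274 to 0.945 for interferon-stimulated genes and 0.354 to 0.945 for antigen presentation genes. Glycolysis and hypoxia genes ranged from 2.95e-06 (lower, without BPTF sh2 replicate 2) to 0.901, and were higher without BPTF sh2 replicate 1. Log2 fold changes that changed sign in those fits ran from −0.10 to 0.0051 for GATA3, −0.058 to 0.24 for CCND1, −0.33 to 0.47 for CDKN1A, −0.0040 to 1.12 for HIST1H1B, −0.050 to 0.73 for PKM2, −0.51 to 0.030 for CD74, −0.034 to 0.58 for PMP22 and −0.26 to 0.56 for KRT19, which was also −0.016 with the trend removed. At these depths a gene at 0 counts is limited to at most 0.585 CPM.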

Other observations

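The classes and genes in this part were chosen after the data were seen, as were the tests on near copies and on the length trend of the lower genes, on MYCNOS and its neighbours and on ATF4 targets. Genes for the mitochondrion were lower as classes picked by symbol. The adjusted p-values below cover the picked classes alone. They are not independent support, since the same libraries were seen before the choice. The 83 nuclear subunits of the respiratory chain had a median log2 fold change of −0.24, with 64 lower (camera adjusted p = 1.21e-08 at the preset correlation, 0.287 with an estimated one). The 75 mitochondrial ribosomal proteins had a median of −0.24, with 53 lower (camera adjusted p = 3.05e-05, and 0.287). The 35 proteasome subunits had a median of −0.09, with 20 lower (camera adjusted p = 0.00321, and 0.306). By fry the unadjusted p-values of these classes were 0.118, 0.0660 and 0.131, in that order. Set by number, the medians in libraries 1 and 2 were −0.57 and −0.09 for the respiratory chain, −0.36 and −0.16 for mitochondrial ribosomal proteins and −0.30 and 0.05 for the proteasome. Of the nuclear 16S rRNA copies, MTRNR2L8 was at 5911 and 5216 CPM in shNT and 10757 and 12691 CPM in BPTF sh2 (log2 fold change 1.08, edgeR adjusted p = 0.0969), MTRNR2L10 at a log2 fold change of 1.05, and MTRNR2L2 at −0.06. The whole family took 1.10% and 1.06% of counts in shNT and 1.74% and 1.77% in BPTF sh2.

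The BPTF sh2 libraries differed from each other more than the controls did. The SD of log2 differences between libraries was 0.594 in BPTF sh2 and 0.367 in shNT, a ratio of 1.62, and 2.51 over the 1974 genes at 100 CPM or more. Glycolysis and hypoxia genes were lower in BPTF sh2 library 1 than in library 2, by a median log2 difference of −0.78. Log2 fold changes from the same-number pairs, which share no library, correlated across genes at r = 0.339 (rho = 0.320), and genes are not independent replicates.

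More genes were lower than higher at an unadjusted p below 0.001, 101 against 9, where 12.2 in all are expected by chance. Reads shared with near-identical copies are argued against as the whole cause, since among genes without a near copy 67 were lower and 4 higher. They may add to it, as 33.0% of the 100 lower genes with a match in the annotation have a near copy, against 23.9% of tested genes. A trend with transcript length or GC content is argued against as the whole cause, since with the trend removed 53 genes were lower and 11 higher at that p, but a part may follow it, as the lower ones fell from 101. Differences between the hairpin-bearing lines, or doxycycline in 1 group only, stay open and were not tested.

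MYCN was lower in both BPTF sh2 libraries. Loss of amplicon copies would lower the antisense gene MYCNOS too, but its log2 fold change was 0.21 (95% interval −0.25 to 0.66), wholly above that of MYCN (−1.59 to −0.51), a comparison that rests on tags assigned by strand. Of 7 tested protein-coding neighbours, 5 had intervals wholly above that of MYCN, among them DDX1 at 0.16 (−0.26 to 0.58) and NBAS at 0.08 (−0.32 to 0.49), while FAM49A at −0.38 (−1.07 to 0.31) and VSNL1 at 0.15 (−0.53 to 0.82) overlapped it, and the data do not show which of them the amplicon holds. With the length and GC trend removed MYCN was at −1.09 with an SE of 0.28 (edgeR adjusted p = 0.189). One hypothesis is that less BPTF lowers MYCN transcript, and with 1 hairpin and a weak reduction of BPTF it was not tested further.

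Ribosomal protein, respiratory chain and mitochondrial ribosomal protein genes, 236 in all, had a median log2 fold change of −0.24. Set by number, ribosomal protein medians in BPTF sh2 libraries 1 and 2 were −0.48 and 0.01. Those of the respiratory chain were −0.57 and −0.09, and those of mitochondrial ribosomal proteins −0.36 and −0.16. Each class was thus lower mainly in library 1. The transcripts of these genes are short, with a median of 1179 nt. With the length and GC trend removed the median of the 236 genes was −0.14 (95% bootstrap interval over genes −0.20 to −0.07). That interval leaves out the spread between libraries, since member genes are not independent replicates. A part of the shift may follow length. Whether most of it does cannot be told apart, because the interval includes the bound of −0.12. A rule written before this test took that bound from the observed median before removal. Shared reads are open too, since the 69 members without a near copy (median −0.16, interval −0.33 to −0.07) hold 0 cytosolic ribosomal proteins, and the median went from −0.24 to −0.11 for the 31 respiratory chain genes left but only from −0.24 to −0.23 for the 38 mitochondrial ribosomal proteins left. Doxycycline, which blocks mitochondrial translation, could act if only BPTF sh2 cells received it, and while ATF4 targets had a median of 0.091 and a mean of −0.04, the conflicting labels keep this open.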
